A study of Mus musculus with 2 samples.

How the data were processed

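Polyadenylated RNA of whole mouse lung at stage E14.5 was sequenced in 2 libraries, 1 from control lungs and 1 from lungs labelled as Prmt5 knockdown. Each library was made from a pool of 7 lungs, per the series design text, with TRIZOL extraction and the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the mouse build mm10. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes and of near-identical copies, such as the globin and Serpina1 genes, are therefore uncertain.

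The authors deposited a table of raw read counts per gene and a table of FPKM values (fragment counts scaled to gene length and library total) for the same 41709 genes. In the deposited tables, FPKM equalled the count divided by a gene length and by the library's total count. The implied lengths were whole numbers within 0.001 bp in 100% of the 22831 genes with reads in both libraries, so the FPKM table holds no measurement beyond the counts apart from these lengths. Genes carry NCBI numbers, apart from 138 entries without one. Of all entries, 40269 were matched to a symbol through the RefSeq genes of GRCm38.p6, the assembly that mm10 stands for, and coordinates are given on that assembly. These genes held 99.8% of the reads in each library. Exon lengths came from the union of exons in the GENCODE annotation of GRCm38 and were available for 93.1% of the measured genes.

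Counts were divided by effective library sizes from the trimmed mean of M values (edgeR 4.0.16, R 4.3.3), with factors of 1.04 for the control and 0.963 for the knockdown library. The ratio of knockdown over control was formed with a prior count of 0.5, scaled to library size. Its 95% interval was the exact Clopper-Pearson interval of the 2 counts given their sum. Such intervals, and the floor of 3 counts used for a library with 0 reads, cover counting error only and not differences between pools. The intervals can be too narrow even for counting error, since PCR copies are not independent molecules. A gene was measured when at least 1 library held 50 reads. It passed the rule of size when the ratio was at least 1.5, or its inverse, and the interval excluded 1. With 1 library per group no spread between replicates exists, so no p-value is given, no difference has a replicate check, and counts of genes describe these libraries rather than the genotypes. Leaving out a replicate or splitting the samples another way was not possible.

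Gene lists numbered 40: arginine methyltransferases and PRMT5 partners, BMP ligands with receptors and antagonists, BMP targets, hedgehog, FGF, WNT, retinoic acid, NOTCH and TGF-beta signalling, p53 targets, apoptosis regulators, S phase, G2/M, Sm proteins with the SMN complex, integrated stress response, hypoxia and glycolysis, immediate early, germline and lung Hox genes, branching matrix genes, common reference genes, Y-linked genes with Xist, and 18 marker lists of cell types and neighbouring organs. A list's median log2 ratio over measured members was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile is a description of the 2 libraries. Named genes were Prmt5, Shh and Bmp4, the 12 highest and 12 lowest genes ranked by the interval bound nearest to 1 (predicted genes, pseudogenes, histones and sex-linked markers left out), up to 4 members of each list past the rule ranked the same way, and members past the rule that went against their list's median. Where no member passed, up to 2 members with the most reads were to be named. Some genes that this rule takes are not reported here, and counts and medians include them. The 40 lists, the naming rule, the size rule and most of the other settings tried were fixed before the data were examined. Of the tests of explanations, some were written before their own values were seen and the others afterwards. A further 9 lists (adrenal cortex, kidney, thymocytes, pancreas, intestine, brain, lung mesenchyme regulators, and held-out lists of liver and of heart and striated muscle) and 3 alternative settings were added afterwards. The held-out lists were written down before any of their values were seen.

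The scripts were tested on simulated counts for the 41709 genes. Of 50 genes given each fold in the knockdown-over-control comparison, the rule recovered 52% at 1.5-fold, 100% at 2-fold, 100% at 4-fold and 96% at 0.5-fold. Random splits of the summed counts, drawn 100 times, passed 23.9 genes as higher and 22.0 as lower on average. Alternatives covered scaling (total counts, DESeq2 1.42.0 size factors, totals without red blood cell and mitochondrial genes), the prior count, the deposited FPKM with 2 pseudocounts, the read minimum, the ratio, the interval, the mean in place of the median, unmatched random lists, a removed top member, a length and GC trend, and ratios relative to the general epithelium list. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.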

Results

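Whole-lung polyadenylated RNA from C57BL/6 mouse embryos at stage E14.5, when the lung is branching, was compared between 1 control library and 1 library labelled Prmt5 knockdown, each from a pool of 7 lungs. The sample title of the second library names Shh and Prmt5, and the labels do not say how either gene was altered or in which cells. The control library held 22581490 counted reads and the knockdown library 25829281. At least 1 read was counted for 24983 genes in the control and 25522 genes in the knockdown library, and 14569 genes reached 50 reads in at least 1 library. All ratios below are knockdown over control with a 95% counting interval, from 1 library per genotype and without replicates.

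The comparison addresses whether lowering Prmt5, a symmetric arginine methyltransferase that modifies histones, alters lung branching genes and releases a Bmp gene from repression. Prmt5 (NCBI gene 27374, chromosome 14, 54507182 to 54517470) had 2704 reads in the control and 2127 in the knockdown library, a log2 ratio of -0.43 (-0.51 to -0.35), which is 1.35-fold lower and not past the rule of size. Shh (NCBI gene 20423, chromosome 5, 28456840 to 28467101), the hedgehog ligand of the lung epithelium, went from 1124 to 109 reads, 10.9-fold lower (log2 -3.44, -3.75 to -3.17). Bmp4 (NCBI gene 12159, chromosome 14, 46383525 to 46390669), a ligand of the distal lung bud, had 1345 and 1096 reads and was 1.30-fold lower (log2 -0.38, -0.50 to -0.26), not past the rule. Relative to the median of the general epithelium list, which was itself lower (-1.55), Prmt5 stood at 1.12 and Bmp4 at 1.17. Subtracting that median makes any gene near the median of all measured genes (-0.01) positive. The sign of both therefore depends on the reference, and the positive values do not by themselves show a rise. The 12 measured arginine methyltransferases and PRMT5 partners ran from Carm1 (-0.62) to Prmt2 (0.20, named after its value was seen), with a median of -0.25. The part of Prmt5 that was targeted is not given in the labels, and whether the lower reads, counted over the whole gene in whole lung, are particular to Prmt5 is not settled by 1 library per genotype.

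Across the genome, 3020 genes were higher and 1795 lower past the rule, together 33.0% of the measured genes. Of these, 1073 were at least 4-fold higher and 162 at least 4-fold lower. None of 100 random splits of the same reads passed more than 35 genes as higher or 32 as lower at the ratio of 1.5, or any gene at 4-fold. Such splits hold counting noise only and not the difference between separate pools, so they do not bear on the genotype. Liver and heart transcripts were among the highest genes. The share of higher genes depended on scaling. It was 62.7% with the main scaling, 52.3% with total counts, 53% and 55.8% with FPKM at pseudocounts of 0.1 and 1, 54.2% when the scaling left out genes nearly silent in the control, and 65.4% with DESeq2 size factors. A stricter bar, a ratio of 2 under the main scaling, gave 74.4%. Total counts shifted the median of all measured genes by -0.11 on the log2 scale, so small list medians below are relative to that choice.

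Genes of liver, heart and skeletal muscle, which the labels do not name, were far more abundant in the knockdown library. All 11 measured liver genes were higher, with a median log2 ratio of 7.44 and single values between 7.14 and 8.45. The serum protein Alb had 474 and 105934 reads (log2 7.72, 7.59 to 7.85), the fetal serum protein Afp 534 and 88862 (log2 7.29), and the fibrinogen chain Fgb 20 and 7604 (log2 8.45). The liver list took 0.00612% of control reads (exact interval 0.00580% to 0.00645%) and 1.03% of knockdown reads (1.026% to 1.034%). All 18 heart muscle genes were higher (median 5.66), among them the myosins Myh7 (log2 8.47), Myl2 (7.80) and Myl3 (7.71) and the natriuretic peptide Nppa (8.09), and the list's share of reads went from 0.0279% to 0.830%. Nppb had 0 control reads and 583 in the knockdown library, at least 183-fold higher against a floor of 3 reads in the control. All 12 skeletal muscle genes were higher (median 5.27), including Ckm (5.96), Mylpf (5.46), Acta1 (5.37) and Myh3 (5.27). In the list of oesophagus, stomach, thymus and thyroid genes 8 of 9 were higher (median 3.06), with the thymus epithelium genes Psmb11 (32.1-fold higher) and Foxn1 (2 and 62 reads, log2 4.57, 2.96 to 7.95), the stomach mesenchyme gene Barx1 (3.49) and Pax1 (0 and 281 reads, at least 88.4-fold higher), and Hoxa3 lower (-0.98). These 4 medians stood at or above the 99.9th percentile of matched random lists, and placing genes without control reads at their floor left them at the same values. Among the 12 highest genes, the aldo-keto reductase Akr1b7 had 1 and 2311 reads (log2 10.52, 8.61 to 16.39), the vitamin C enzyme Gulo had 0 and 653 (at least 205-fold higher), and Kng1 (8 and 4610 reads), Itih3 (13 and 4462 reads) and the fibrinogen chain Fga (30 and 8284 reads) encode plasma proteins. In the control library 4 of the 11 liver genes, 11 of the 18 heart genes and 6 of the 12 skeletal muscle genes also reached 50 reads.

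Blood, immune, neural and mesothelial genes were higher as well. Of 16 red blood cell genes 14 were higher and none lower (median 2.22, percentile 100), led by Hemgn (6.05), Rhag (6.02), Klf1 (5.60) and Gata1 (4.97), transcripts of immature red cells. Their share of reads was 1.21% in the control and 3.87% in the knockdown library. Of 17 immune genes 14 were higher and none lower (median 1.22, percentile 100), with Laptm5 (3.08), Cd74 (2.45), Ptprc (1.84) and Lyz2 (1.29). Among 16 nerve and glia genes 13 were higher (median 1.28, percentile 99.97, or 94.88 with the mean), including Phox2a (2.02), Tubb3 (1.89) and Prph (1.77), and Erbb3 (-1.04) and Ret (-0.67) were lower. Of 12 mesothelium genes 8 were higher and none lower (median 0.88, percentile 99.97, or 96.47 with the mean), with Msln (3.10), Bnc1 (1.72), Lrrn4 (1.43) and the transcription factor Wt1 (1.13). Among 6 lymphatic endothelium genes Reln (3.56), Thy1 (2.15) and Prox1 (2.13) were higher and Mmrn1 (-1.24) and Flt4 (-0.62) lower (median 1.14, percentile 99.84). That percentile was 76.2 without the member of largest ratio and 93.9 with the mean. Prox1 also marks liver cells.

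Lung epithelial genes were lower in the library that carried the other organs' genes. Of 26 general epithelium genes 21 were lower and none higher (median -1.55, percentile 0). The lung lineage factor Nkx2-1 went from 7550 to 895 reads, 8.94-fold lower (log2 -3.16, -3.26 to -3.06), and Epcam (-2.36), Cdh16 (-2.36) and Foxa1 (-2.26) were lower as well. In the distal tip and alveolar list 10 of 19 genes were lower and 7 higher (median -0.60, percentile 0.01, or 3.10 with the mean). The surfactant gene Sftpc was 7.17-fold lower (8880 and 1313 reads, log2 -2.84) and Muc1 9.32-fold lower. The higher members were Slc34a2 (3.36), Hopx (2.25), Ager (2.83-fold, with an authors' length 2.43 times its annotated exons), Lyz2 (1.29), Napsa (1.20), Bex2 (0.87) and Abca3 (0.71). Of these, Lyz2 is also a member of the immune list. Set against the general epithelium median, the distal list turned to 0.95. The proximal airway list split, with 7 of 13 higher and 5 lower (median 1.69, percentile 99.97). Its mean was 0.35, at percentile 43.8. The stratified epithelium keratins Krt5 (3.54) and Krt14 (3.35) were higher, whereas Scgb3a2 (-3.61), Aldh1a7 (-3.44), the airway factor Sox2 (-1.85), Tspan1 (-1.77) and Cyp2f2 (-1.43) were lower. Of 7 neuroendocrine genes 4 were higher, among them Chgb (3.73), Chga (3.38) and Scg5 (2.47), and 1 was lower (median 0.76, percentile 86.4, or 99.87 and 55.6 with read minima of 10 and 200 and 97.98 unmatched).

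Mesenchymal and vascular lists showed both directions. Among 22 lung mesenchyme genes 7 were higher and 6 lower (median 0.23, percentile 99.63, or 71.0 with the mean and 94.95 unmatched). The matrix and fibroblast genes Twist1 (2.86), Dpt (2.35) and Postn (2.31) were higher, whereas Tbx4 (-2.06), Wnt2 (-2.02), Foxf1 (-1.87), Tbx5 (-1.28), Meox2 (-1.17) and Tcf21 (-0.76), which pattern the lung mesenchyme, were lower. Of 14 Hox genes of lung 11 were lower and none higher (median -0.96, percentile 0), including Hoxb5 (-1.65), Hoxb3 (-1.60), Hoxa6 (-1.59) and Hoxb6 (-1.30). In the endothelium list 6 of 18 genes were lower and none higher (median -0.50, percentile 0.03), with Sox17 (-1.47), Robo4 (-1.22), Sox18 (-0.72) and Esam (-0.70). Smooth muscle genes had 2 higher and 4 lower of 13 (median -0.27, percentile 8.24, or 1.79 with the mean), with Myh11 (-1.43) and Mylk (-1.36) lower and Des (1.72) and Cnn1 (0.68) higher. Pericyte genes had 2 higher and 3 lower of 8, Abcc9 (1.23) and Rgs5 (0.70) against Notch3 (-1.25), Pdgfrb (-0.80) and Cox4i2 (-0.77), and the list median of 0.03 turned negative under total counts, with or without red blood cell and mitochondrial genes, FPKM, scaling without genes nearly silent in the control, a minimum of 10 reads and the mean. Cartilage genes had 3 higher and 3 lower of 12 (median -0.11, percentile 25.2), with Acan (2.31), Comp (2.24) and Sox6 (1.66) higher and Sox5 (-2.56) lower. Of 23 branching matrix genes 12 were lower (median -0.62, percentile 0), including Frem1 (-1.90) and the laminin chains Lama3 (-1.86) and Lama1 (-1.36), while Timp3 (0.79) and Fn1 (0.77) were higher.

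**Figure D1:**
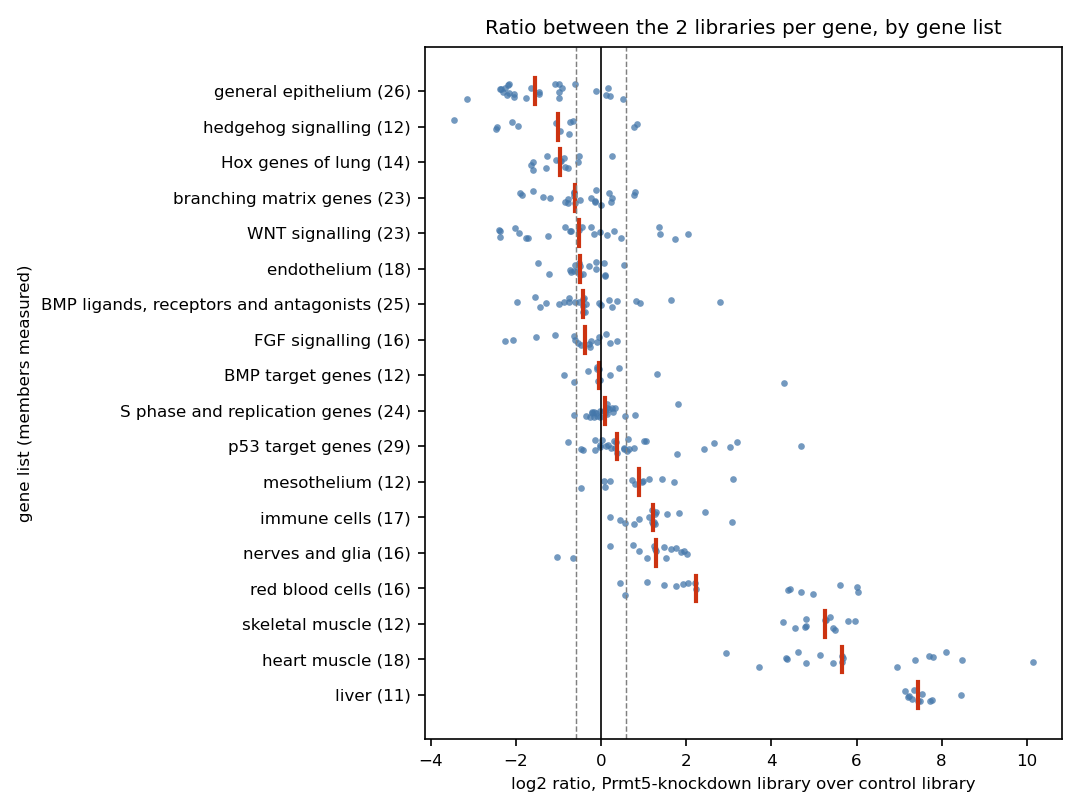
Each point is a measured gene of a list, placed by its log2 ratio of the knockdown over the control library (horizontal axis), and red bars are list medians. Dashed lines mark the ratio of 1.5 and its inverse. The liver list has its median at 7.44, the general epithelium list at -1.55 and the hedgehog list at -1.02, and the S phase median of 0.09 turned negative under total counts, FPKM and a removed length and GC trend.

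Hedgehog pathway genes were lower along with the epithelial ligand. All 12 measured members passed the rule, 10 lower and 2 higher (median -1.02, percentile 0). Beside Shh, the hedgehog-induced genes Hhip (5.48-fold lower, log2 -2.45) and Gli1 (4.28-fold lower, log2 -2.10) were among the lower genes. The ligand-binding co-receptors Gas1 (0.84) and Cdon (0.76) were higher. These libraries also differed in lung epithelial genes as a whole. Relative to the general epithelium median, Shh stood at -1.89.

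BMP pathway genes went both ways, and Bmp4 was not higher with the main scaling (-0.38). Its value of 1.17 relative to the general epithelium median comes from subtracting that lower median and does not by itself show a rise. Of 25 measured ligands, receptors and antagonists 9 were lower and 4 higher (median -0.42, percentile 0.03). The ligand Bmp3 (-1.55) was among the lower genes, and the antagonist Fst (2.80) and the ligands Bmp6 (1.65), Bmp2 (0.92) and Bmp7 (0.83) were higher. Of 12 BMP target genes 2 were higher, the heart factor Tbx20 (100 and 2103 reads, log2 4.30) and Msx1 (1.32), and 2 lower, Id4 (-0.88) and Smad7 (-0.64). The target list's median was -0.06 (percentile 43.5) and its mean 0.34, so the direction of this list is not defined. The library with the higher BMP ligands, Fst and Tbx20 also carried the liver, heart and muscle genes. Which tissue the reads of these higher genes came from was not tested.

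**Figure D2:**
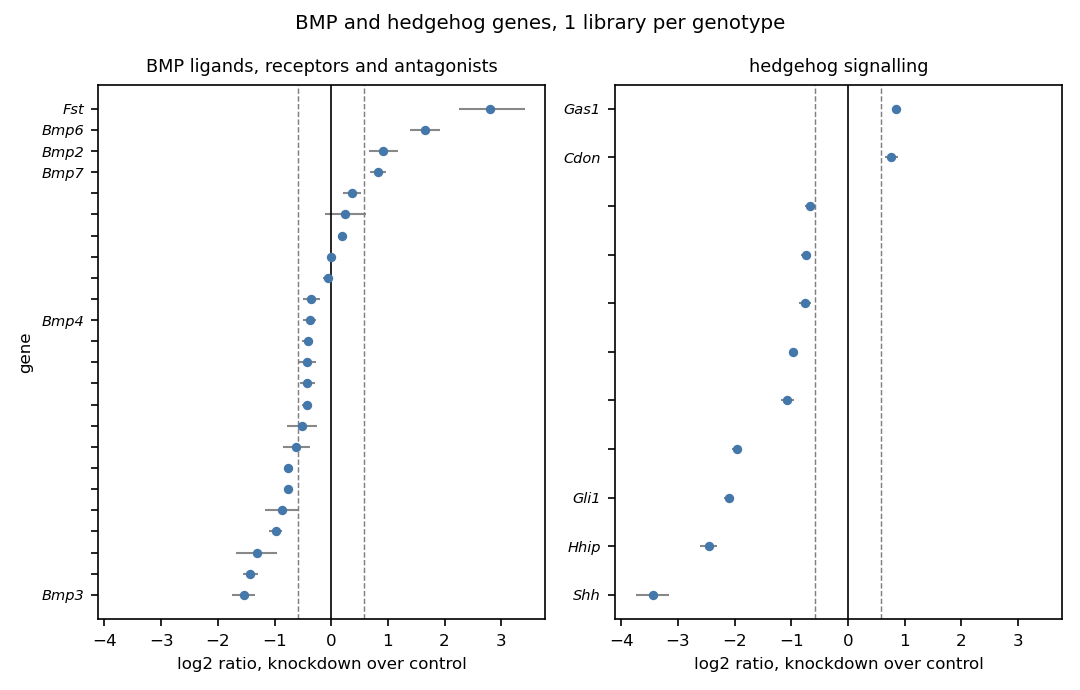
Log2 ratio of the knockdown over the control library (horizontal axis) for the measured genes of the BMP list (left) and the hedgehog list (right), without genes that are not reported here and with names for those in the text. Bars are 95% counting intervals from 1 library per genotype, and dashed lines mark the ratio of 1.5 and its inverse. Shh lies lowest at -3.44, and Bmp4 lies at -0.38, inside the dashed lines.

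FGF and WNT lists had more lower than higher genes, and other branching signals went both ways. General epithelium genes were lower in the same library (21 of 26, median -1.55), and a lower value of an epithelial signalling gene is to be read beside that. Higher values are likewise to be read beside the liver, heart and muscle genes that this library carried. Of 16 FGF genes 6 were lower and none higher (median -0.38, percentile 0.41, or 3.01 without genes of excess length and 3.08 without the member of largest ratio), with the receptors Fgfr3 (-2.26) and Fgfr2 (-1.52) and the FGF-induced factors Etv5 (-2.07) and Etv4 (-1.08). Of 23 WNT genes 11 were lower and 4 higher (median -0.51, percentile 0). Lgr6 (-2.40), the epithelial ligand Wnt7b (-2.38), Sp5 (-2.38) and the mesenchymal ligand Wnt2 (-2.02) were lower, and Rspo3 (2.04), Dkk2 (1.73), Wnt4 (1.40) and Sfrp1 (1.36) higher. NOTCH genes had 4 lower and 2 higher of 14 (median -0.31, percentile 2.27), Notch4 (-1.81, with a length 1.61 times its exons), Notch3 (-1.25) and Notch2 (-0.70) against Hey2 (2.45) and Dll1 (0.76). The NOTCH percentile left the lowest tail with FPKM at a pseudocount of 1 (3.42), without genes of excess length (4.87), with the mean (6.68), with the length and GC trend removed (9.97) and with read minima of 10 and 200. TGF-beta genes had 3 lower and 2 higher of 15 (median -0.14, percentile 30.8), Tgfbi (-0.85), Ltbp2 (-0.79) and Smad3 (-0.68) against Ccn2 (0.92) and Ccn1 (0.70). Retinoic acid genes had 5 higher, among them Cyp26a1 (3.27), Aldh1a3 (1.81) and Crabp1 (1.76), and 3 lower of 14, Aldh1a1 (-1.26) among them. Their median was -0.02, turning to 0.01 with DESeq2 size factors, and their mean 0.35.

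Genes linked to Prmt5 loss in other tissues include p53 targets. Of 29 measured p53 targets 12 were higher, 1 was lower and 16 did not pass the rule (median 0.38, percentile 99.87, or 98.6 with the mean). Gdf15 was 26.1-fold higher (10 and 290 reads), the cell cycle inhibitor Cdkn1a 9.10-fold (153 and 1480 reads, log2 3.19, 2.95 to 3.44), Perp 8.19-fold and the apoptosis activator Pmaip1 6.30-fold, whereas Plk2 was 1.72-fold lower. Integrated stress response genes had 6 higher and 1 lower of 15 (median 0.47, percentile 99.74), with Asns (1.78), Atf3 (1.60) and Nupr1 (1.22) higher and Cebpb (-0.92) lower. Hypoxia and glycolysis genes had 6 higher and 1 lower of 16 (median 0.41, percentile 99.63), with Ndrg1 (2.32), Adm (1.83), Pdk1 (1.15) and the glucose carrier Slc2a1 (2.83-fold) higher and Vegfa (-0.82) lower. Immediate early genes had 6 higher and 2 lower of 14 (median 0.52, percentile 99.05), with Fosb (2.11), Fos (1.78) and Dusp1 (1.03) against Egr3 (-1.51) and Jun (-0.59). With the mean, the percentiles of the last 3 lists were 81.7, 86.2 and 71.6. The library with these genes higher also carried the liver, heart and muscle genes.

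Few genes passed the rule in the lists of the cell cycle, cell death and the methylation machinery. Of 12 arginine methyltransferases and PRMT5 partners 1 passed the rule, Carm1 (1.54-fold lower, log2 -0.62), and the median was -0.25 (percentile 8.80, or 0.31 with the length and GC trend removed). Apoptosis regulators had 2 higher and 1 lower of 19, Cycs (0.96) and Bcl2l1 (0.77) against Bcl2 (-0.98), S phase genes 2 higher and 1 lower of 24, Cdc45 (1.80, in the chromosome 16 stretch described next) and Rrm2 (0.79) against Pole (-0.63), and reference genes 3 higher of 12. The medians of these 3 lists, 0.01, 0.09 and 0.08, turned negative under total counts, FPKM and a removed length and GC trend. Those of the apoptosis and reference lists also did so when scaling left out genes nearly silent in the control, that of the apoptosis list under totals without red blood cell and mitochondrial genes and with the mean, and that of the reference list without its member of largest ratio. Among the reference genes the glycolytic enzyme Gapdh had 528 and 5190 reads (log2 3.21, 3.08 to 3.34), a count made uncertain by its processed pseudogenes, with B2m (0.84) and Hprt (0.61) also higher. G2/M genes had 1 higher, Kif11 (1.34), and 2 lower of 25, Ttk (-0.61) and Kif20a (-0.60), with a median of -0.21 (percentile 13.9). Sm protein and SMN complex genes, which include substrates of PRMT5, had 1 higher, Gemin5 (0.89), and 2 lower of 18, Lsm4 (-1.67) and Smn1 (-1.20), with a median of -0.11 (percentile 29.0, or 0.06 with the length and GC trend removed). Only 3 of 16 germline genes were measured, with Mov10l1 (4 and 246 reads, log2 5.70) higher and Asz1 (-2.73) lower (median -0.12). Of Xist and 4 Y-linked genes, Xist (-0.85) was lower and Uty (0.70) higher. The median of these 5 was 0.52 (percentile 91.2), but it joins Xist with Y-linked genes, which went opposite ways, so it has no clear direction. The sex make-up of the pools was not examined beyond these genes.

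The lowest genes were of several kinds. Cckar, the cholecystokinin A receptor (16.4-fold lower), Tinag (20.7-fold), Vwa2 (14.6-fold) and the transcription factor Ets2 (14.7-fold) were among the 12 lowest. So were broadly expressed genes, the phosphatase subunit Ppp1ca (2010 and 121 reads, 17.5-fold lower), the transcription factor subunit Taf11 (22.5-fold) and the respiratory chain subunit Ndufs3 (13.6-fold). A further 4, Zdhhc8 (617 and 21 reads, 30.4-fold), Dgcr2 (20.2-fold), Septin5 (16.9-fold) and Scarf2 (14.7-fold), lie together on chromosome 16 between 17797282 and 18876637 (mm10). In this stretch 14 of 16 measured genes passed the rule, 7 higher and 7 lower, with a median absolute log2 ratio of 1.86. In the stretch before it, 17070139 to 17722947, 2 of 20 passed, with a median of 0.21. On chromosome 17, between 33523646 and 37074305, 52 of 81 measured genes passed, 23 higher and 29 lower, with a median absolute log2 ratio of 0.96, and 35 had an authors' length over 1.5 times the annotated exons. Notch4 and Ager lie there. By chromosome, such measured genes were most frequent on 17 (45) and 11 (44), with 7 on 16. The bounds of these stretches were chosen after the values were seen. Of the genes named in this text, Zdhhc8, Nppa, Nppb, Wnt2, Notch4, Ager and Cox4i2 had an authors' length over 1.5 times the annotated exons, which makes their counts less certain.

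**Figure D3:**
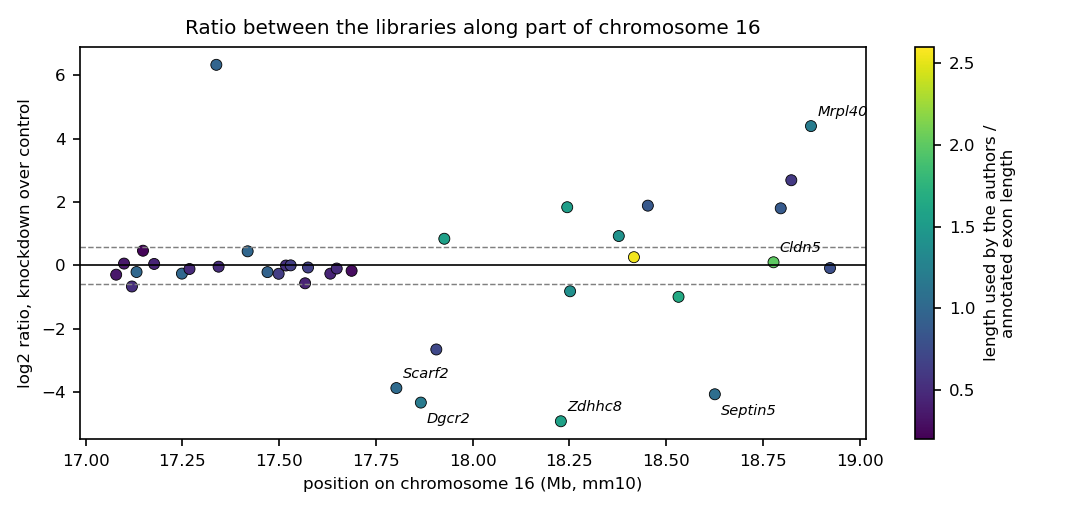
Log2 ratio of the knockdown over the control library (vertical axis) for measured genes along chromosome 16 (horizontal axis, Mb on mm10), coloured by the length used by the authors over the annotated exon length. Dashed lines mark the ratio of 1.5 and its inverse. Zdhhc8 at -4.93 and Mrpl40 at 4.40 lie in the stretch where 14 of 16 genes passed the rule.

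Ratios from the deposited FPKM and from counts had a Pearson correlation of 0.987 across measured genes at a pseudocount of 0.1, with a median absolute difference of 0.00335 on the log2 scale after removing the common shift. Genes are not independent replicates, and both tables come from the same reads. As FPKM is the count over a fixed length and the library total, the correlation reflects only the scaling and the pseudocount. For the same reason, FPKM and total counts are the same scaling among the alternatives. Over the 40 lists fixed before the data were examined, 15 medians lay above and 10 below the central 95% of matched random lists.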

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

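The settings that left out genes of excess length, scaled without genes nearly silent in the control or left out members of other-organ lists were chosen after seeing the data. Leaving out the other-organ lists gave 2943 higher and 1794 lower genes. This dropped only the members of the liver, heart, skeletal muscle, red blood cell, immune and oesophagus, stomach, thymus and thyroid lists. The change was thus fixed by how many members had passed the rule, and unlisted genes of those organs stayed in. It does not measure how many of the higher genes come from other organs. The number of higher genes moved from 3020 to 1956 with a minimum of 200 reads, and the number of lower genes from 1795 to 3560 at the lower ratio tried and to 703 at a ratio of 2, since these settings test fewer genes or set another bar. Prmt5 (-0.43) moved to -0.54 with total counts, -0.54 and -0.53 with FPKM at pseudocounts of 0.1 and 1, and -0.52 when scaling left out genes nearly silent in the control, in step with the shift of all genes. Relative to the general epithelium median, Prmt5 moved to 1.12, Bmp4 to 1.17 and Shh to -1.89, and the distal list reversed to 0.95, because that median of -1.55 was subtracted. With FPKM at a pseudocount of 1, Shh moved to -3.001, the liver median to 6.64 and the skeletal muscle median to 3.74 (4.76 at 0.1), as a pseudocount shrinks genes low in 1 library. The mean of the p53 targets was 0.81. With means in place of medians, 7 rather than 15 lists lay above the central 95% of random lists, and the cause was not tested. The proximal, lung mesenchyme, stress, hypoxia, immediate early, mesothelium, lymphatic and nerve lists were the ones lost. The germline list, with 3 genes, went from percentile 28.6 to 1.42 without its member of largest ratio. The FPKM correlation was 0.915 at a pseudocount of 1. Mean and median differed in sign for the BMP target, retinoic acid, apoptosis, germline, pericyte and cartilage lists. The cartilage median (-0.11) turned to 0.13 without its member of largest ratio, the cartilage and BMP target medians turned to 0.16 and 0.03 with the length and GC trend removed, and the germline median to 0.25 with a minimum of 10 reads and, on few genes, 5.70 with 200. Of the other values for main results, 183 stayed within their bounds. Among single named genes and the remaining lists, 1332 values stayed within their intervals, 255 moved and 1 reversed. Counted as reversed is a change of sign in a gene past the rule or in a list outside the central 95% of random lists. Among the values computed, only the distal list showed it. The setting relative to the general epithelium median was run on no lists but the distal, proximal and neuroendocrine ones. Subtracting -1.55 would also turn other low lists positive, such as hedgehog (-1.02) and lung Hox genes (-0.96). The other changes of sign among the computed values were in lists inside that range, or in genes not past the rule. Depth limits genes near 50 reads, as for Msx1 with 22 and 59 reads and an interval from 0.61 to 2.12.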

Other observations

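The 9 lists reported here were added after the main results were seen. The predictions on other organs' tissue, on a general opening of silent genes and on gene models were written before their own values were seen. Those on tissue and on silent genes use lists among these 9, so they also followed the main results. All other tests were added after the main results were seen. The bound for Shh was widened from a point value to a counting interval after a first look. The test on lung Hox genes replaced an earlier one on the lung mesenchyme regulators, picked from the pattern itself. For the third pattern, a test on the lowest genes of excess length and one on counting noise were dropped, the first for the same reason and the second because the read minimum all but fixed its outcome. All 7 adrenal cortex genes were higher in the knockdown library (median log2 ratio 4.56, or 3.97 with genes at 0 control reads placed at their floor). The steroid hormone genes Cyp11a1 (20 and 575 reads, log2 4.73) and Star (69 and 833 reads) and the adrenal factor Nr5a1 (6 and 162 reads, log2 4.56) were among them. All 4 measured thymocyte genes of 7 were higher (median 5.96, or 4.64 at the floor), with Rag1, which rearranges antigen receptor genes, at 4 and 187 reads (log2 5.30). Few genes of the other added organs reached 50 reads. They were 1 of 8 for kidney (Six2, log2 3.54), 1 of 10 for brain (its value is not reported here), 1 of 6 for intestine (Lgals4, log2 0.10) and 2 of 6 for pancreas (with Cpa1 at 1.09). The 6 lung mesenchyme regulators, picked after their values were seen, were all lower (median -1.58), which bears on no explanation. Cbx7, chosen after its values were seen, took 1.66% of control reads and 2.66% of knockdown reads.

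Genes of other organs in the knockdown library form the first pattern. A candidate explanation is tissue of other organs in the pool: of the 22 measured genes of the held-out liver (median 6.21) and heart and striated muscle (median 5.13) lists, predicted before their values were seen, 95.5% were at least 4-fold higher. A general opening of silent genes was argued against by the brain and intestine lists, of which 12.5% reached 50 reads in the knockdown library. In unscaled counts the liver median was 7.52, which a difference in library size, whose log2 value was 0.19, cannot give. This is the scaled median of 7.44 without the scaling, so it is not separate evidence. Whether RNA of other organs entered the pool stays open, since the held-out genes do not separate such tissue from another source of the RNA or an effect of the genotype, with 1 library each, and the control also held such reads (Alb 474, Afp 534).

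Lung genes lower in the knockdown library form the second pattern. If other organs' tissue took part of the pool, a smaller share of lung RNA could lower lung genes alike. The general epithelium median minus that of the lung Hox genes was -0.59, larger than the interquartile range of the Hox list and smaller than that of the epithelial list, so a smaller lung share cannot be told apart from a genotype effect. A smaller lung share alone predicted Shh within the interquartile range of the epithelial list (-2.17 to -0.94), and Shh lay below it (-3.44). The opposite prediction also failed, as the upper bound of Shh lay 0.10 above the lower bound of Nkx2-1, the lowest epithelial gene. Against the point value of Nkx2-1 (-3.16), the upper bound of Shh (-3.17) lay below, so that outcome depends on the bound. A loss of Shh beyond that of the epithelium thus cannot be told apart either.

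Broadly expressed genes with extreme ratios, as on parts of chromosomes 16 and 17, form the third pattern. A candidate explanation is genes present more than once in the authors' gene models, with reads lost where copies match. The test took the 206 genes with at least 50 control reads whose length exceeded 1.5 times the annotated exons. Of these, 5.83% were at least 4-fold lower (exact interval 3.05% to 9.95%), 3.63 times the 1.61% of other genes matched on expression. The 206 genes include members of the chromosome 16 and 17 stretches, such as Zdhhc8 and Notch4. These stretches are part of the pattern, so the test is not independent of it. The excess ran in both directions, with 4.37% against 2.19% at least 4-fold higher and median absolute log2 ratios of 0.48 and 0.32. The minimum of control reads leaves out genes that rise from few control reads, so these shares do not compare the directions evenly. Of all 271 measured genes of excess length, 92 were higher and 57 lower past the rule, against 3020 and 1795 of all 14569 measured genes. Lost copies alone would lower a gene in both libraries alike, and Dgcr2, Ppp1ca and Septin5 lay under the length bound, so a difference between the libraries in mapping or sequence stays open, as does the genotype.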
